A study of Homo sapiens with 2 samples.

How the data were processed

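Total RNA of tumour tissue was labelled with Cy3 and hybridised to Agilent one-colour human arrays, 1 array for p-Cont and 1 for p-T-miR-7, per the labels. Whether each RNA came from a single tumour or from several is not given in the sources used here, nor is the split of the 8 mice between the plasmids. The labels state a plasmid dose of 100 mg. Per the file headers, both arrays came from the same slide and were read under the same extraction protocol, so slide and scan did not separate the groups.

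The deposited scanner files hold each spot's intensity on a linear scale, background-subtracted and detrended within the array by Agilent Feature Extraction, per the file headers. The headers name version 11.0.1.1 of that program, and the submitters' processing notes name version 9.1. The authors' series matrix holds log2 values, 1 row per probe. Set against the scanner values, its columns matched a quantile normalization of the log2 signals of both arrays, with a median absolute difference of 0.0004 and a correlation over probes of 0.98 for the log2 ratio. Its columns had medians of 5.7509 for p-Cont and 5.7505 for p-T-miR-7, and both ran in the direction of the signal.

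Control spots and spots flagged as non-uniform or as population outliers were left out, which flagged 266 of 43118 non-control spots on the p-Cont array and 264 on the p-T-miR-7 array. No probe was saturated on either array. Spots of the same probe were averaged on the log2 scale. Each array's 75th percentile over non-control probes was then subtracted. A probe was measured where it was well above background on both arrays, and 25513 probes were. The lowest signal well above background was 9.07 on the p-Cont array and 9.23 on the p-T-miR-7 array, against medians of 2.21 and 2.14 for negative control spots.

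Probes were named by RefSeq accession through a table of genes of assembly GRCh38.p14, used for names only because the array design was built on hg19; coordinates are therefore not given. Of 34125 probes 25766 matched a gene (75.5%), among them 23856 of 24462 probes with an NM accession. The 8359 other probes entered the scaling but no gene count. A gene took the value of its brightest measured probe, and 15780 genes were measured. Where a gene's probes went at least 1.5-fold both ways, that is stated. Most probes had a single spot, and the spread over the spots of repeated probes covers measurement within an array and not the spread between mice. Human probes can also bind RNA of the mouse host, which was not measured apart.

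Genes were called higher or lower by a rule of size, 2-fold, without a test. A total of 31 gene lists were fixed before the data were examined. For each, the median log2 ratio was set against 10000 random lists of the same size, drawn in 20 bins of mean level (2000 for most alternatives). Its percentile describes these arrays and is not a p-value, since genes are not replicates. For genes well above background on 1 array only, the fold is a lower bound. It sets the brighter signal against the higher of the dim probe's own signal and the lowest signal well above background on the dim array.

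Named genes follow a rule that was also fixed before the data were examined. It takes the 12 highest and 12 lowest log2 ratios among genes with an NM accession above the median of probes well above background on at least 1 array. It adds genes named beforehand whatever their values, among them EGFR, IRS1, IRS2, PAK1, NDUFA4 and NKX2-1. It adds for each list up to 2 highest and 2 lowest members at least 2-fold apart, and the 3 largest bounds each way. Some genes that the rule takes are not reported here.

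The steps were tested on simulated data, in which 200 genes were changed on a copy of the p-Cont array. With a scatter of SD 0.19, 100.0% of the genes changed 4-fold passed the 2-fold rule in both directions, with 0 of 15580 unchanged genes past it. With the scatter between probes of the same transcript (SD 0.77), 90.0% of the genes raised 4-fold and 92.0% of those lowered 4-fold passed. Of genes changed 2-fold, 40.0% to 56.0% passed over both scatters. Of 100 random lists, 8 at the smaller and 3 at the larger scatter lay outside the percentiles 2.5 to 97.5.

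Alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median log2 ratio, an intensity-dependent loess with a span of 0.3, the authors' log2 values, the mean over a gene's probes, no filter on dim probes, and only genes above the median level on both arrays. Normexp was run on the median spot signal in place of the mean spot signal named beforehand, which was not used here. Calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. A shift of genes with a miR-7 seed site in the 3' UTR was foreseen and not run, because transcript sequences were not used here.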

Results

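Gene expression was measured in tumours that human lung cancer 95D cells had formed under the skin of Balb/c nude mice, a strain that lacks a thymus. The mice had received plasmid injections in the opposite flank, either p-T-miR-7 or the control plasmid p-Cont. Per the labels, 8 mice were used, and the plasmid was given 5 times at intervals of 3 days, starting 7 days after the cells. Tumours were taken 3 days after the last injection. One-colour arrays with human probes were hybridised with tumour RNA, with 1 array for p-T-miR-7 and 1 for p-Cont. With 1 array per group the difference has no replicate check, so values and folds are given without a test, and the number of arrays limits the precision.

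On the p-Cont array 27808 of the 34125 non-control probes were well above background (81.5%), and on the p-T-miR-7 array 26055 were (76.4%). The p-T-miR-7 array was dimmer, with a 75th percentile of signal of 191 against 361. This gap widened with brightness and narrowed again among the brightest probes. The unscaled log2 ratio of p-T-miR-7 over p-Cont had a median of −0.37 among the dimmest probes, with mean log2 signals up to 5, of −1.48 at mean log2 signals of 11 to 13, and of −1.31 above 13. Levels below are log2 signals relative to each array's own 75th percentile, and log2 ratios are p-T-miR-7 minus p-Cont.

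The comparison of p-T-miR-7 with p-Cont asks how the tumour transcriptome differed after a plasmid named for the microRNA miR-7. As lists, transcripts of oxidative phosphorylation, mitosis, protein folding and cholesterol synthesis were lower on the p-T-miR-7 array than random lists of their level. With second-brightest probes, mitosis, heat shock and respiratory complex I came inside percentiles 2.5 to 97.5, and ER stress stayed outside. Cholesterol synthesis and complexes III to V had no such value. Marker lists of myeloid cells, lymphocytes, and muscle, fat and skin were higher than their random lists. Each of these marker lists came inside percentiles 2.5 to 97.5 under some alternative. Gene families expected to be silent also had a median above 0 (0.61, against 0.27 in their random lists). Of 15780 measured genes, 2657 were at least 2-fold higher and 2979 were at least 2-fold lower, leaving 10144 between. Genes on the lower side had a median level of 0.69, against −1.28 for those on the higher side. Centring on the median log2 ratio gave 2033 higher and 3712 lower genes, so that 35.4% rather than 47.1% of the genes past the rule were higher. A simulation with the scatter seen between probes of the same transcript (SD 0.77 on the log2 scale) put 1532 of 15580 unchanged genes past the rule as higher and 1536 as lower.

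**Figure D1:**
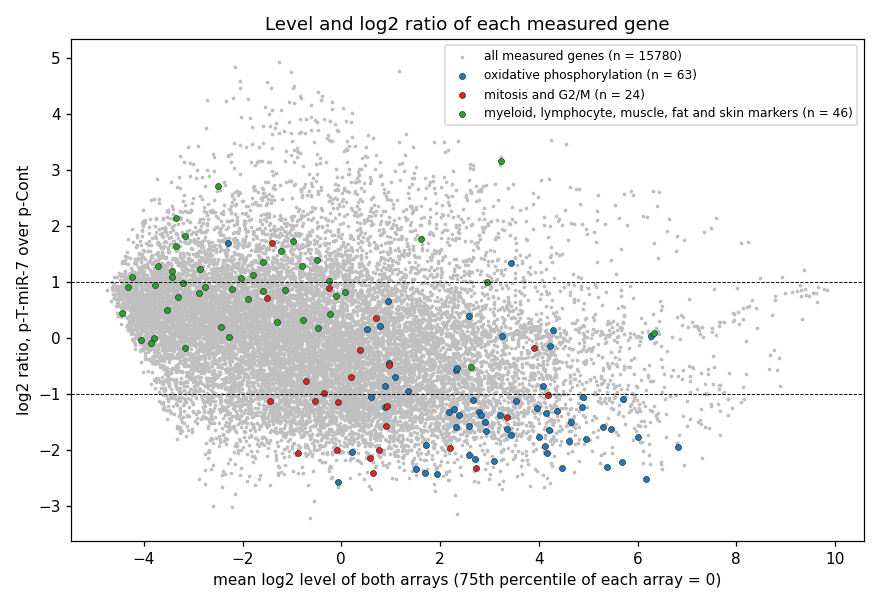
Each point is a gene, with its mean log2 level over both arrays on the x axis and its log2 ratio of p-T-miR-7 over p-Cont on the y axis, and dashed lines mark 2-fold. Most oxidative phosphorylation genes (blue, 63 genes) lie below 0 and most myeloid, lymphocyte, muscle, fat and skin markers (green) lie above 0 at low levels.

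Spots of the same probe agreed closely, and different probes of the same transcript did not. The median SD of the log2 ratio over repeated spots was 0.06 among 790 probes with 10 spots. For 2871 transcripts with at least 2 measured probes, the log2 ratios of the 2 brightest probes differed by a median of 0.61, and 30.5% differed by at least 2-fold. Among the 563 genes at least 2-fold higher that had a second probe, 32.3% had all probes past the rule, and among the 783 lower genes 38.3% did. This left 182 higher and 300 lower genes with all of at least 2 probes past the rule.

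**Figure D2:**
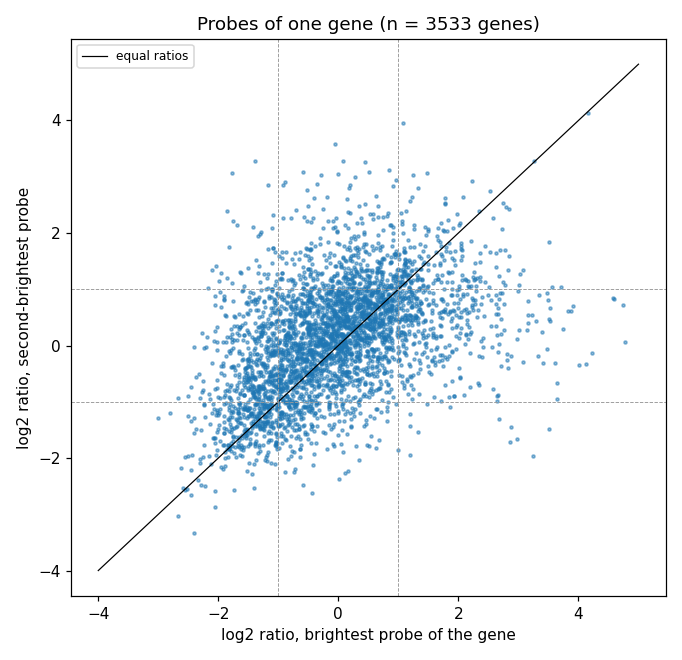
Each of 3533 points is a gene with at least 2 measured probes, with the log2 ratio of its brightest probe on the x axis and that of its second-brightest probe on the y axis; the line marks equal ratios and dashed lines mark 2-fold. Many genes far to the right lie well under the line, with a median second-probe log2 ratio of 0.73 for the genes at least 2-fold higher.

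Among genes above the median level on at least 1 array, the 12 lowest had log2 ratios of −3.22 to −2.67. DNAJB9, a chaperone of the endoplasmic reticulum, was 9.30-fold lower. CHCHD2, a mitochondrial protein, was 8.81-fold lower. CKS1B, a cofactor of cyclin-dependent kinases, was 6.99-fold lower by its brightest probe and had a log2 ratio of −1.20 by its second. UQCR11, a subunit of respiratory complex III, was 6.52-fold lower, and ACSL3, which activates long-chain fatty acids, was 6.51-fold lower. The others were TMSB15A (8.09-fold), the zinc transporter SLC30A7 (8.00-fold), LRP12 (7.54-fold), FGF12 (6.87-fold), RPL26L1 (6.66-fold), MANEA (6.37-fold) and TMEM106B (6.35-fold). Of these 12 genes 4 had a second probe, and in 3 it was also at least 2-fold lower, with TMEM106B at −3.02. With normexp background correction the 12 genes ran from −3.08 to −0.94 and 11 stayed past 2-fold, with TMSB15A at −1.22, FGF12 at −1.12, SLC30A7 at −1.05 and MANEA at −0.94.

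The 12 highest genes had log2 ratios of 4.29 to 4.93 and were dim on the p-Cont array, with levels of −4.57 to −2.55. With normexp they ran from 2.37 to 3.23. They were BMP3, a secreted factor of bone, the collagen gene COL6A5, the T-cell and neuronal transcription factor BCL11B, RNF208, the transcription factor NFIC, the mucin-type glycosyltransferase GCNT3, the hair keratin KRT40, HEATR4, the olfactory receptor OR4C46, the protease MEP1A, TMEM178B and KALRN. BMP3 was 30.58-fold higher by its brightest probe, and its other probe was not well above background on either array. Second probes were measured for BCL11B, RNF208 and NFIC, and read 0.71, 0.83 and 0.84. The other KRT40 probe was not well above background on either array, so it gives no second reading. Another KALRN probe, for a different transcript, was well above background on the p-Cont array only. Its levels were low, at −4.58 on p-Cont and −5.31 on p-T-miR-7. It gives no fold, but it did not follow the rise of the brightest KALRN probe.

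Published targets of miR-7 did not stand apart from other genes of their level. Of 30 measured targets, 5 were at least 2-fold higher, 8 at least 2-fold lower (5 with loess) and 17 between. Their median log2 ratio was −0.21, against −0.17 in random lists matched on level (percentile 43.99). The random lists had an SD of 0.25, so a shift of the targets within about 2 SD could not be told from their spread. The amount of miR-7 itself was not examined here. PFN2, which binds actin, was 5.00-fold lower and CKAP4 4.28-fold lower, whereas the transcription factor KLF4, dim on the p-Cont array at a level of −4.88, was 9.47-fold higher (log2 ratio 3.24, and 1.42 with normexp) and the kinase gene TNK2 4.21-fold higher, the latter with a second probe at 0.91. PAK1 had a log2 ratio of −0.16 and IRS2 of −0.25 (0.44 with normexp). IRS1 was 1.99-fold lower, with a second probe at −0.77. The brightest EGFR probe, for a shorter transcript variant (NM_201283), was 4.05-fold higher. The repeated EGFR probe for the full-length receptor (NM_005228) had a log2 ratio of −0.40 (SD 0.11 over spots), and the remaining EGFR probe one of 1.26. NKX2-1 was not well above background on either array, and no probe was matched to NDUFA4.

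Genes of oxidative phosphorylation were lower together. In complex I, the entry point of the respiratory chain, 26 of 37 measured genes were at least 2-fold lower (16 with loess) and 1 was higher. The median log2 ratio was −1.34, against −0.45 in matched random lists (percentile 0.00). NDUFA13 was 5.40-fold and NDUFB6 5.04-fold lower. In complexes III to V, 20 of 26 genes were lower (13 with loess) and 1 higher, with a median of −1.51 (percentile 0.00). ATP5F1C, a subunit of ATP synthase, was 5.92-fold lower, UQCRH was 5.75-fold lower with a second probe at −2.54, and ATP5F1A was 2.53-fold higher. Ribosomal protein genes, which are also short and abundant, had a median of −0.92 against −0.51 in their random lists (percentile 2.80, and 1.09 with loess), with 18 of 40 lower (11 with loess) and 0 higher. Their second-brightest probes, measured for 19 genes, lay on the other side, 0.30 above random lists, where the brightest probes lay −0.41 from theirs, and −0.67 with quantile normalization. RPL30 was 4.42-fold lower (spot SD 0.07), and RPS23 was 4.06-fold lower by its brightest probe with a second at 0.33.

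Among the cell division lists, mitosis genes lay below percentile 2.5 under all scalings and DNA replication genes under some of them, and histones lay within percentiles 2.5 to 97.5. Of 24 measured genes of mitosis and G2/M, 14 were at least 2-fold lower and 1 higher, with a median of −1.13 against −0.25 in random lists (percentile 0.06). Second probes of 5 of these genes lay −0.32 from random lists (percentile 29.36). The checkpoint kinase gene TTK was 5.31-fold lower and the cyclin gene CCNB1 5.02-fold lower, with a second CCNB1 probe at −0.50. The mitotic kinase gene PLK1 went the other way on both of its probes, at 1.70 and 1.46. Among 25 genes of DNA replication and S phase, 9 were lower and 0 higher, with a median of −0.85 (percentile 2.40, and 7.26 with loess). The ribonucleotide reductase subunit RRM1 was 5.61-fold lower and PCNA, the sliding clamp of DNA polymerase, 3.48-fold lower, with PCNA probes at −1.80 and −1.79. Replication-dependent histones had a median of −0.82 (percentile 4.38), and 4 of 16 were lower and 0 higher. The linker histone gene H1-2 was 2.47-fold lower.

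Genes of protein folding and sterol synthesis followed. In the endoplasmic reticulum stress list 11 of 20 genes were lower and 1 higher, with a median of −1.29 against −0.30 in random lists (percentile 0.01). Besides DNAJB9, HERPUD1 was 4.62-fold lower, and EDEM1 was 2.22-fold higher. Of 19 heat shock genes 10 were lower and 1 higher, with a median of −1.24 (percentile 0.04). The distance from random lists was −1.04, −0.70 with loess and −0.31 (percentile 32.65) for second probes of 5 genes. The chaperone genes HSPA4L and HSPH1 were 5.70-fold and 4.79-fold lower, the second HSPH1 probe read −1.98, and HSPA1L was 2.41-fold higher. In cholesterol synthesis 13 of 21 genes were lower and 0 higher, with a median of −1.22 (percentile 0.02). CYP51A1, an enzyme of late sterol synthesis, was 4.28-fold lower. The hypoxia and glycolysis list had a median of −0.76 (percentile 1.66, and 7.83 with the mean over probes), with 13 of 29 genes lower (8 with loess) and 1 higher. ANKRD37 was 3.67-fold and PGK1 3.42-fold lower, while the glycolysis regulator PFKFB3 read 4.01 on its brightest probe and −0.34 on the other. Housekeeping genes as a list had a median of −0.91, against −0.47 in their random lists (percentile 4.74), and 10 of 26 were lower (6 with loess) and 1 higher. EMC7 was 4.30-fold lower and GPI 2.25-fold higher.

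Apoptosis genes had a median of −0.59 (percentile 8.23), with 9 of 25 lower and 3 higher. BID, which links caspases to mitochondria, was 4.67-fold lower, with probes at −2.22 and −2.50. The death receptor gene FAS was 6.95-fold higher, and its 3 probes read 2.80, 2.45 and 1.58. BMF was 6.23-fold higher by its brightest probe, but its probes disagreed in direction, with the other at −0.99. The p53 target list, which also holds FAS, had a median of 0.09 (percentile 66.46) that ranged from −0.09 to 0.24 over the scalings, with 2 of 19 genes higher and 2 lower. Second probes of 7 of these genes lay 0.79 above random lists (percentile 95.73). SFN was 2.09-fold higher and RRM2B 3.03-fold lower. BAX probes disagreed in direction, at −1.18 for the brightest and 2.85 for the other.

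Signalling lists showed no common direction beyond random lists. Immediate early and ERK feedback genes had a median of 0.09 (percentile 68.91; −0.08 to 0.16 over the scalings), with 5 of 25 higher and 2 lower (4 with loess). The ERK inhibitor gene SPRY4 was 7.06-fold higher with a second probe at 1.34, EGR3 was 5.78-fold higher, JUN was 2.74-fold lower and SPRED1 2.09-fold lower, the last with no change with normexp (−0.004). RAS, RAF and MAPK pathway members had a median of −0.27 (percentile 19.16), with 4 of 28 higher and 6 lower. EGFR counted as higher through its brightest probe, and its mean over probes was 0.96. ARAF, dim on the p-Cont array at a level of −4.77, was 2.93-fold higher. It was under 2-fold with loess (0.95) and normexp (0.83). GRB2 was 3.15-fold lower (−0.93 with normexp), and RPS6KA3 was 2.95-fold lower with a second probe at −0.75. PI3K, AKT and mTOR pathway members had a median of −0.05 (percentile 64.52; −0.23 to 0.07 over the scalings), with 4 of 28 higher and 5 lower (2 with loess). TSC1 was 4.41-fold higher and PIK3CD 3.68-fold higher with a second probe at 0.44, while EIF4E was 2.58-fold lower on its brightest probe and PIK3R3 2.39-fold lower.

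Among the lists of invasion and cell identity, lung lineage genes alone lay outside percentiles 2.5 to 97.5, and not with loess. Proteases of invasion and their inhibitors had a median of −0.44 (percentile 6.59), with 4 of 20 lower and 0 higher. CTSL was 2.65-fold lower and TIMP2 2.49-fold lower. Angiogenesis factors had a median of −0.64 (percentile 5.44, and 2.35 without a filter on dim probes), with 4 of 19 lower (2 with loess) and 1 higher. The receptor gene NRP1 was 2.44-fold lower and PGF 2.27-fold lower, while NRP2 was 3.19-fold higher. Mesenchymal genes had a median of −0.53 (percentile 11.25), with 3 of 19 lower and 2 higher. VIM, an intermediate filament, was 2.60-fold lower and CDH2 2.31-fold lower, while SPARC was 3.58-fold and AXL 2.26-fold higher. Epithelial genes had a median of 0.27 (percentile 89.16; 0.00 to 0.32 over the scalings), with 3 of 17 higher and 3 lower. Their distance from random lists was 0.36, and −0.12 without a filter on dim probes. The claudin CLDN7 was 8.81-fold higher and MUC1 6.15-fold higher on its brightest probe, with a second at 1.65, whereas the junction genes OCLN and TJP1 were 2.96-fold and 2.86-fold lower. Lung lineage genes had a median of 0.72, against 0.28 in random lists (percentile 97.77), with 2 of 20 higher and 0 lower. With loess the median was 0.26 (percentile 90.21), with 5 higher and 1 lower. The surfactant gene SFTPA2 was 3.62-fold higher on its measured probe, and another SFTPA2 probe was not well above background on either array. The club cell gene SCGB1A1 was 2.53-fold higher.

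Immune response lists were mixed. Interferon response genes had a median of 0.13 (percentile 43.28; −0.05 to 0.35 over the scalings), with 3 of 26 higher and 4 lower. EPSTI1 was 8.14-fold higher (spot SD 0.09). OAS2 read 3.90 on its brightest probe, 0.71 on the second and −0.19 on the other, and IFIT5 and IFIH1 were 3.30-fold and 2.93-fold lower, but under 2-fold with normexp (−0.40 and −0.73). Inflammatory cytokines and NF-kB targets had a median of −0.07 (percentile 24.23; −0.24 to 0.34 over the scalings), with 2 of 15 higher and 3 lower (1 with loess). LIF was 6.87-fold higher with a second probe at 1.08, and CXCL1 read 1.20 and −0.36. BIRC3 was 2.23-fold lower and NFKBIA 2.13-fold lower. MHC class I and antigen processing genes had a median of −0.81 (percentile 7.02), with 6 of 15 lower (2 with loess) and 0 higher. Second probes of 4 of these genes lay on the other side, 1.42 above random lists. The peptide transporter genes TAP1 and TAP2 were 3.08-fold and 2.26-fold lower.

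Among the markers of other cell types, those of myeloid cells, lymphocytes, and muscle, fat and skin lay above percentile 97.5, and those of red blood cells, endothelium and fibroblasts did not. In these tumours of human cells, cells of such types would come from the mouse host, whose RNA was not measured apart. Measured were 17 of 24 listed myeloid, 16 of 20 lymphocyte and 13 of 22 muscle, fat and skin markers. Among those not measured were CD68, LYZ and CTSS, the lymphocyte gene CD79B, and CKM, FABP4 and LEP. The measured members were dim, with median levels of −2.03, −2.47 and −1.79 in the same order of lists. Macrophage and myeloid markers had a median of 0.97 against 0.28 in random lists (percentile 99.69, and 92.42 among bright genes), with 8 of 17 higher (4 with loess) and 0 lower. PTPRC, the pan-leukocyte CD45 gene, was 3.41-fold higher, and its 3 measured probes ran from 0.18 to 2.63. ITGAX was 3.11-fold higher. Lymphocyte markers had a median of 0.85 (percentile 98.80, and 97.40 with normexp), with 5 of 16 higher and 0 lower. The B-cell receptor gene CD79A was 8.92-fold higher and the perforin gene PRF1 6.55-fold higher. Muscle, fat and skin markers had a median of 1.02 (percentile 99.57, and 92.75 without a filter on dim probes), with 7 of 13 higher (4 with loess) and 0 lower. The skeletal muscle actin ACTA1 was 4.41-fold higher (spot SD 0.28) and the fat hormone ADIPOQ 3.55-fold higher (spot SD 0.23). Red blood cell markers had a median of 0.53 (percentile 90.43), with 2 of 10 higher and 0 lower; EPB42 was 15.49-fold higher and SLC4A1 3.24-fold higher with a second probe at 0.37. Endothelial markers had a median of 0.67 (percentile 89.78), with 4 of 12 higher and 0 lower, among them PLVAP (3.17-fold) and ESAM (2.40-fold). Fibroblast and matrix markers had a median of 0.15 (percentile 67.58, and 96.60 with loess; −0.02 to 0.46 over the scalings), with 3 of 19 higher and 2 lower. The distance from random lists was 0.11, and 0.41 with quantile normalization, 0.48 with loess and 0.58 among bright genes. Second probes of 3 of these genes lay 1.40 above random lists (percentile 98.66). ACTA2 was 13.01-fold and COL6A1 2.97-fold higher and FBLN2 2.22-fold lower, while FBLN1 probes disagreed in direction, at −1.76 for the brightest and 2.22 for the second. Taste receptor, keratin-associated, beta-defensin and vomeronasal receptor genes, families used mainly in sensory cells, hair and lining tissues, had a median of 0.61 over 89 genes. Their random lists had 0.27.

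**Figure D3:**
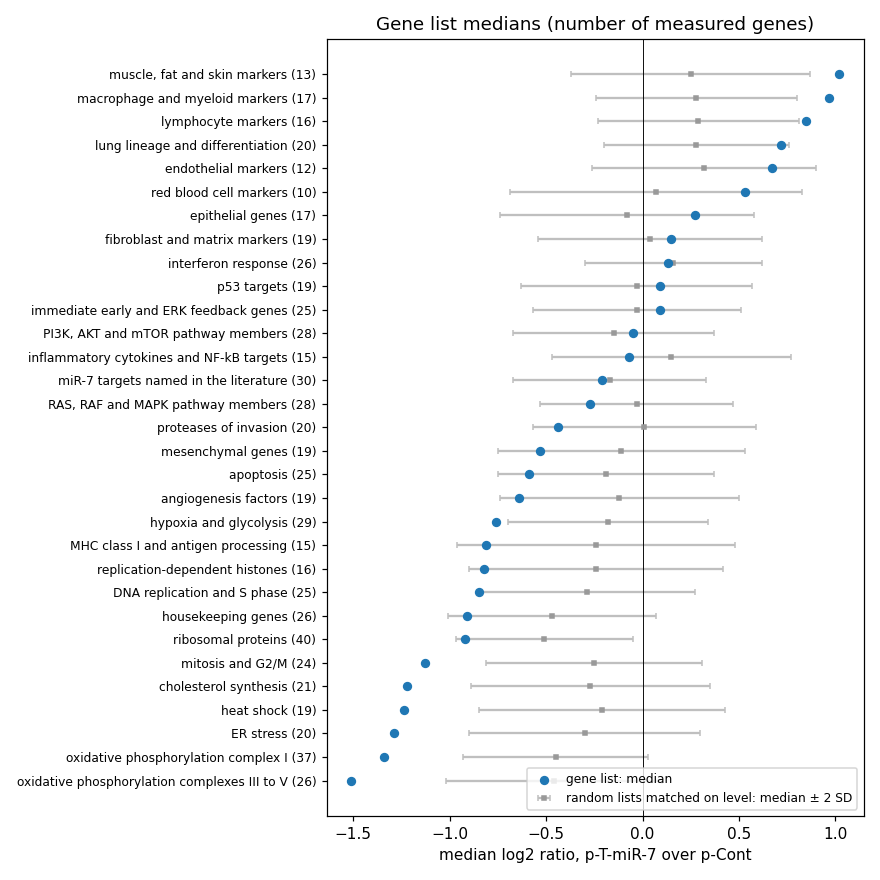
Blue points give the median log2 ratio of p-T-miR-7 over p-Cont for each gene list, with the number of measured genes in brackets; grey squares and bars give the median and 2 SD each way of random lists matched on level. The 2 oxidative phosphorylation lists lie at −1.34 and −1.51 and the muscle, fat and skin markers at 1.02.

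Some genes were well above background on 1 array only. There were 244 such genes on the p-T-miR-7 array and 1049 on the p-Cont array. The p-T-miR-7 array was dimmer (75th percentile 191 against 361), with a similar lowest signal well above background (9.23 against 9.07). The larger p-Cont count therefore does not by itself show a loss of transcripts. The prohormone convertase gene PCSK2 was at least 56.40-fold higher on the p-T-miR-7 array, PRSS48 at least 47.65-fold and the complement receptor gene CR2 at least 46.32-fold. A second CR2 probe was not well above background on either array. EDIL3, a secreted integrin ligand, was at least 6.05-fold lower, NUDCD1 at least 5.95-fold lower and XK at least 5.82-fold lower.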

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

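The tests in this part were chosen only after the values were seen. Control probes, which no comparison of the report uses, were set between the arrays without scaling. The control probe ETG10_13482 had a mean log2 signal of 6.76 (SD 0.12 over 10 spots) on the p-T-miR-7 array. On the p-Cont array most of its spots were not well above background, so the log2 difference is at least 3.58. The spike-in control probe (+)E1A_r60_a107 read 12.55 against 11.08, a difference of 1.46 over 32 spots. Both stood out because they were at least 2-fold brighter on the array that was dimmer as a whole. Of 13 control probes measured on both arrays 4 were higher and 9 lower, from −0.84 to 1.46, with 0.84 as the second highest. Most of them lay near the lowest signal well above background, so they say little about bright probes. The brighter control probe ERCC-00062_278 differed by −0.46. The bright corner control spots differed by 0.15 in their means (SD 0.18 and 0.10 over 14 spots on each array).

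A related pattern is the 155 genes at least 8-fold higher on the p-T-miR-7 array, against 4 at least 8-fold lower. Other probes of the same RefSeq transcript were measured for 33 of the 155, and these 39 probes had a median log2 ratio of 0.67 (bootstrap SD 0.16), where the brightest probes had 3.51. Of these probes 13 passed 2-fold in the same direction. A rise of the whole transcript needs the other probes to follow, and for these 33 genes as a set they followed only in small part. This cannot decide the question. By the rule the other probes were dimmer, and they counted only where well above background on both arrays. Signal of single probes may account for part of the pattern. The remaining genes had no such measured probe. Choosing genes by an extreme probe lowers the second reading by itself. Among genes at least 4-fold lower the other probes had a median of −1.28 against −2.23, and among genes at least 4-fold higher 0.79 against 2.55. The 2 sides were not matched on level, so this gap cannot separate the explanations. Genes at least 2-fold lower had a median level of 0.69, and those at least 2-fold higher one of −1.28. The source of such signal, and any effect of the plasmid on single genes such as FAS, whose 3 probes were all higher, stays open.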

How the results depend on the processing

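Tests with the second-brightest probe or with all of at least 2 probes past the rule were chosen after seeing the data; the other alternatives were set before the data were examined. The count of higher genes was 1485 with normexp, 846 among bright genes, 4633 at 1.5-fold, 1194 at 3-fold and 182 with all of at least 2 probes past the rule, and 2033 to 3370 under the remaining alternatives. The count of lower genes was 1982 among bright genes, 4764 at 1.5-fold, 944 at 3-fold and 300 with all of at least 2 probes, and 2122 to 3712 under the remaining ones. Fewer genes enter the bright and the 2-probe counts; the cause of the normexp drop was not tested. The median log2 ratio of all genes was 0.04 in the main setting, 0.18 with normexp, −0.07 with quantile normalization and the authors' values, −0.14 with median centring and −0.04 with loess.

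The miR-7 target median stayed between −0.38 and −0.01 over the alternatives set beforehand and was 0.047 with second-brightest probes. Its distance from matched random lists was −0.04, and 0.21 among bright genes. The 12 lists outside percentiles 2.5 to 97.5 kept the side of their random lists under each alternative that gave a value, and 6 stayed outside under all alternatives set beforehand: mitosis, both oxidative phosphorylation lists, ER stress, heat shock and cholesterol synthesis. DNA replication came inside with quantile normalization, loess, the authors' values, the mean over probes and bright genes (3.42 to 8.97), and lung lineage with these except bright genes, and with normexp and no filter on dim probes (90.15 to 97.10). Hypoxia came inside with normexp (3.40) and the mean over probes (7.83), lymphocyte markers with normexp (97.40), myeloid markers among bright genes (92.42), and muscle, fat and skin markers there (93.60) and without the filter (92.75). With second-brightest probes 5 of 6 lists with a value came inside; complex I (−1.10) and DNA replication (−0.58) kept their distance there, with a wider spread of random lists. These percentiles rest on 2000 random lists each. Of 19 lists inside in the main setting 4 came outside under some alternative. Ribosomal protein genes did so with normexp, quantile normalization, loess, the authors' values and bright genes (0.00 to 1.95). Angiogenesis factors did so without the filter (2.35), and MHC class I genes (97.85) and fibroblast markers (98.75) with second-brightest probes. With normexp the distance shrank to 0.17 for lung lineage genes, 0.18 for myeloid and 0.18 for lymphocyte markers and 0.34 for muscle, fat and skin markers, the last also 0.34 without a filter on dim probes. Lung lineage genes stood at 1.30 among bright genes. Heat shock genes stood at −0.69 with quantile normalization, −0.70 with loess, −0.70 with the authors' values and −0.29 with second-brightest probes. With second-brightest probes mitosis genes stood at −0.28 and hypoxia genes at −0.13. With normexp the random lists narrowed too, with an SD of 0.12 for myeloid markers against 0.26 in the main setting. The causes of the other moves were not tested. Of 113 named genes past 2-fold, 16 fell under it with normexp, 12 with loess, 8 each with quantile normalization, the authors' values and the mean over probes, and 4 with median centring, and 2 of 56 among bright genes. The ratios that moved by more than the scatter between probes, 33 with normexp and 15 with the mean over probes, all came nearer to 0. BAX and FBLN1 changed sign, to 0.83 and 0.69, in the mean over probes, and PFKFB3, at −0.34, among bright genes, where another probe stands for the gene.

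Some lists had too few bright members or second probes for a value. The seed-site shift and its alternatives were not run. No paired analysis was possible because each group had 1 array. Dim genes are limited by signal over background, and small lists by the scatter between probes.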

Other observations

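The tests of silent gene families and of second probes of marker genes were set before their own values were seen, though olfactory receptor genes and second probes of other genes had been looked at by then. The second-probe test of the lower lists was set after second probes of some of its genes, such as UQCRH and CCNB1, had been seen. The loess and ribosomal protein tests, the reading of second probes as undecided where their spread takes in the whole shift, and the choice of the genes in the next paragraph also came after.

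Genes whose measured probes all passed 2-fold, ranked by the probe nearest 0, give a view that rests on at least 2 probes. The 8 lowest were TMEM106B (−2.67 for its nearer probe), the malate dehydrogenase gene MDH1 (−2.55), TMEM14C (−2.53), UQCRH (−2.52), the splicing factor SNRPG (−2.45 over 3 probes), MEIOC (−2.40), the mitochondrial ribosomal protein MRPL12 (−2.28) and BID (−2.22). The 8 highest were GOLGA6L10 (3.27), MPRIP (2.53), TMEM145 (2.52), the Wnt ligand WNT3A (2.42), the glutamate receptor subunit GRIK3 (2.35), the signalling kinase IRAK1 (2.22), HIVEP3 (2.07) and the read-through transcript ARPC4-TTLL3 (2.03).

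The mitosis and oxidative phosphorylation lists, pooled over 87 genes, lay −0.93 from matched random lists. These random lists were matched on level, so a trend with brightness between the arrays would move both alike. The distance therefore argues against such a trend as the whole cause. The distance after loess, −0.91 (SD 0.16), adds little, because the matching had already taken up a trend of this kind. Signal of single probes cannot be told apart from a change of the transcripts, because only 12 of these genes had a second probe, and those lay −0.59 (SD 0.38) from random second probes. Loss of short transcripts also stays open: the oxidative phosphorylation lists lay −0.52 (SD 0.30) further down than ribosomal protein genes, less than 2 SD, and second probes of the ribosomal list lay on the other side of their random lists (0.30). An effect of the p-T-miR-7 plasmid was not tested, since each group was 1 array.

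The markers of myeloid cells, lymphocytes, red blood cells, muscle, fat and skin, pooled over 56 genes, had a median of 0.84. A candidate explanation is a general rise of probes for silent genes: the 89 taste receptor, keratin-associated, beta-defensin and vomeronasal receptor genes had a median of 0.61, above their own random lists (0.27, SD 0.12), and the markers exceeded them by only 0.23 (SD 0.19). Signal of single probes cannot be told apart from it, with second probes of 7 marker genes at 0.44 (SD 0.44) from random second probes. More cells of these types in the p-T-miR-7 tumour tissue stay possible and were not tested here. Several listed markers, such as CD68, LYZ and FABP4, were not measured. The tumours were formed by human cells, so such cells would come from the mouse host. Human probes can bind RNA of the host, which was not measured apart.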
